A study of Mus musculus with 2 samples.

How the data were processed

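The data were H3K9me3 ChIP-seq peak lists from mouse hindbrain at embryonic day 13.5, in 1 group with 2 biological replicates numbered in the labels. The group was taken from the labels, which give the same tissue, age and antibody target for both. According to the descriptions deposited with the files, the pooled list was derived from the alignments of both replicates, and the replicated list from the pooled list and the lists of the replicates. Coordinates are in mm10, per the labels. The aligner, the peak caller, its version and its threshold are not given in the sources used here. A control experiment is named in the labels and was not analysed here.

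Each peak list gave, per peak, the position, an enrichment value, significance values and the summit. The enrichment is a value by the authors, read here as a ratio (fold) over the caller's background. That reading rests on the file format and on the values, since the caller is not named, and it holds for every fold enrichment printed. The significance values are the −log10 p-value and −log10 q-value deposited by the authors. The smallest −log10 p was 2.02 in replicate 1, 2.0 in replicate 2 and 2.02 in the pooled list, so weak peaks were kept. The share of peaks with a −log10 q of at least 2 was 21.5% in replicate 1, 25.5% in replicate 2, 55.5% in the pooled list and 92.6% in the replicated list. Enrichment values were used to describe, rank or filter peaks within their own list, and were compared between lists only as a correlation over overlapping peaks of the replicates. Because only peak lists were used, the depth of each library is unknown, and a place without a peak cannot be separated from a place with too few reads. A difference in the number of peaks between replicates may follow from depth and was not read as a difference in the mark.

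The reference was the soft-masked GRCm38.p6 genome with the GENCODE M21 annotation, the same assembly as mm10, and every peak ended within the length of its chromosome. Main comparisons used chromosomes 1 to 19, X and Y. The 268 replicated peaks on unlocalized and unplaced contigs were left out of them, because the expected values came from shifts along chromosomes. Replicated peaks, of which 29360 lay on the chromosomes, were the main list. Values from each replicate's own list are given as mean ± SD with n = 2.

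Overlaps counted from 1 bp. The expected values came from circular shifts: all peaks of a chromosome were moved by 1 random offset, with runs of N removed, so that the spacing of peaks was kept. There were 1000 shifts for replicate overlap, genomic features, sequence content and primer sites, and 10000 for gene lists. Permutation p-values were two-sided, and the smallest possible were 0.002 and 0.0002. Shifts do not match GC content or the share of unique sequence. Summits were assigned to 1 of 6 features, with promoters at 1 kb either side of a transcription start site. A gene counted as marked when its annotated body overlapped a peak. The 13 gene lists were fixed before the data were examined, by symbol family (zinc finger, olfactory receptor, vomeronasal receptor, clustered protocadherin, Hox, ribosomal protein, histone cluster and cytochrome P450 family 2 genes) or by name (imprinted, germline, hindbrain and neural, other cell types in the tissue, and other organs). All named members were found in the annotation. Benjamini-Hochberg adjustment covered the 13 lists, the 6 features or the 5 primer types. Wilson intervals cover counting error only, at a level of 95%.

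Gene ends were compared with an exact sign test on genes of at least 5 kb. Primer binding sites were exact matches on either strand to textbook sequences of 18 bases, namely TGGTGCCGAAACCCGGGA (Phe), TGGCGCCCAACGTGGGGC (Lys1,2), TGGCGCCCGAACAGGGAC (Lys3), TGGGGGCTCGTCCGGGAT (Pro), TGGTGTCAGAAGTGGGAT (Leu), TGGAGGCCCCACCGAGAT (Gln) and TGGAGGTCCCACCGAGAT (Gln variant). Types with fewer than 10 matches were not tested. Domains were replicated peaks joined across gaps of up to 5 kb. The named genes followed a rule fixed before the data were examined. It took the 10 protein-coding genes of at least 1 kb with the highest share of the body covered and a peak in each replicate, and the 10 genes holding the peaks of highest enrichment. It also took up to 2 members of each list with the most covered bases, and the 5 domains with the most covered bases with the protein-coding genes in them.

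The alternatives were other lists, thresholds, overlaps, windows, gaps and tests, and the list of each replicate alone. Some were added after the data were seen: peaks overlapping both replicates, peaks of unique sequence, peaks placed at random individually with and without matching for GC content, a peak on the longest coding exon, and 1 kb either side of the transcript end. A peak was of unique sequence when 5 sequences of 32 bases around its summit each occurred once in the genome, which held for 20280 peaks (69.1%). The shift test for gene lists was tested on simulated data from 21938 genes. Of 200 random lists of 50 genes, 14 (7.0%) had a p below 0.05, and all 20 lists given peaks in a further 20% of their members were found. All lists were scored on the same simulated peaks, which had equal width and included the added ones. The 7.0% is therefore not a clean rate of false calls. The lists were scattered over the genome, so the rates were not tested for families of clustered genes. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.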

Results

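Trimethylation of lysine 9 of histone H3 (H3K9me3), a mark of transcriptionally silent heterochromatin, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the hindbrain of mouse embryos at embryonic day 13.5. The tissue came from the strain B6NCrl, with male and female embryos pooled. All libraries belonged to 1 group with 2 biological replicates, made of 1 technical replicate in replicate 1 and 2 in replicate 2. There was no second condition, so the comparisons were between the replicates, and between the positions of the peaks and positions reached by shifting the peaks along their chromosomes. Sequencing depth is unknown from peak lists, and with 2 replicates no test between replicates was made. The list of replicate 1 held 88416 peaks, and that of replicate 2 held 62633 peaks. Their peaks on the chromosomes covered 24.28 Mb and 17.05 Mb. The authors also gave 95043 peaks called on the pooled replicates and 29628 replicated peaks. The 29360 replicated peaks on the chromosomes covered 15.53 Mb, or 0.587% of the chromosomes. These had a median width of 430 bp and a median enrichment of 3.81-fold, where the enrichment is the authors' value for each peak. The strongest replicated peak, at 17.1-fold, lay on Klf14, which encodes a Krüppel-like transcription factor.

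The first comparison asked how far the replicates marked the same places. Of the replicate 1 peaks on the chromosomes, 29.77% (26193 of 87995) overlapped a replicate 2 peak by at least 1 bp, against 1.48% ± 0.22 (SD over 1000 circular shifts). In the other direction, 42.43% (26415 of 62251) of the replicate 2 peaks overlapped a replicate 1 peak, against 2.1% ± 0.32 after shifts. The Jaccard index of the covered bases was 0.174, against 0.00467 ± 0.0009. For all 3 values the two-sided permutation p was 0.002, the smallest that 1000 shifts can give. Requiring an overlap of 50% in both directions lowered the shares to 14.58% and 20.61%. Across 20134 pairs of peaks that overlapped one to one, Spearman's rho of the enrichment in the replicates was 0.151 and Pearson's r of its log2 was 0.193. With 50% reciprocal overlap rho was 0.215 and r was 0.269, and for peaks with a −log10 q of at least 2 they were 0.228 and 0.371. This correlation is across peaks, which are not independent replicates, and it has no p-value. All 29628 replicated peaks stood in the pooled list with the same position and values. Of these, 24202 (81.7%) overlapped a peak of both replicates and 105 overlapped none.

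H3K9me3 peaks lay outside genes more often than shifted peaks, and in introns less often. Of 29360 replicated summits on the chromosomes, 58.7% were intergenic, against 49.9% ± 1.5 (SD over 1000 shifts). Introns held 29.8%, against 40% ± 1.4, and coding exons held 1.7%, against 1.05% ± 0.092. These differences had a permutation p of 0.004 after Benjamini-Hochberg adjustment over the 6 features. Promoters, taken as 1 kb either side of a transcription start site, held 7.13%, against 6.66% ± 0.4 (adjusted permutation p = 0.342). UTRs held 1.43% and other exons 1.23%, and neither passed the test (adjusted permutation p = 0.342 for both). With the pooled list the UTR and promoter shares fell below the shifts, at 0.867 and 0.908 of the shifted share (adjusted permutation p = 0.015 and 0.0216). With peaks at or above the median enrichment they passed above the shifts, at 1.3 and 1.17 (adjusted permutation p = 0.021 and 0.0336). Other exons then passed as well, at 1.21 (adjusted permutation p = 0.046). The peaks were richer in G and C than shifted peaks, with 45.0% against 42.1% ± 0.28 (permutation p = 0.002). Soft-masked repeats made up 33.1% of the bases in peaks, against 33.9% ± 0.78 after shifts, which was not a detectable difference (permutation p = 0.252). Peaks at or above the median enrichment had 32.3% against 33.9% (permutation p = 0.038). Those of unique sequence had 27.0% against 33.8% (permutation p = 0.002), under a filter that leaves out repeated sequence. Shifts do not match unique sequence, which made up 90.7% of 32-base sequences around summits and 81.2% of those at random positions. An excess in repeats is therefore not excluded.

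Chromosome 7 carried the densest replicated peaks, and the sex chromosomes the sparsest. Chromosome 7 held 31.9 replicated peaks per Mb, 15.4% of all replicated peaks, against 11.1 per Mb over all chromosomes. Chromosome 17 was next with 21.7 per Mb, followed by chromosome 4 with 16.2 and chromosome 13 with 15. Chromosome X held 3.16 per Mb and chromosome Y held 0.204. The gap for chromosome X was smaller in the single lists. It had 19.8 per Mb against 33.2 over all chromosomes in replicate 1, and 14.7 against 23.5 in replicate 2. Male and female embryos were pooled and depth is unknown, so fewer peaks on X and Y are not shown to mean less of the mark. The lists of the single replicates placed chromosome 7 first as well, with 65.0 ± 13.3 peaks per Mb (SD, n = 2), against 48.5 ± 11 on chromosome 17. These are values with no test, since chromosomes are not replicates.

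**Figure D1:**
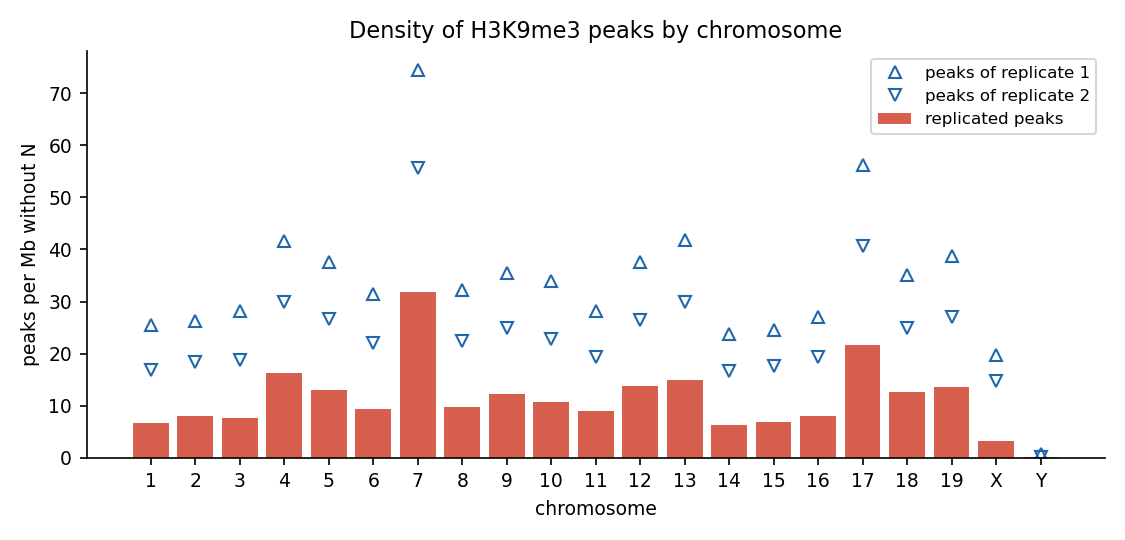
Peaks per Mb of sequence without N on each chromosome (y axis, peaks per Mb), with bars for the replicated peaks and triangles for the lists of replicates 1 and 2. Chromosome 7 stands highest, at 31.9 replicated peaks per Mb, and chromosome Y lowest, at 0.204.

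Peaks also gathered into domains. Replicated peaks joined across gaps of up to 5 kb gave 16000 domains, of which 881 held at least 5 peaks and together 33.0% of the peaks. The domain with the most covered bases lay on chromosome 18, from 37653468 to 37777836 (mm10), over the gamma protocadherin cluster except its end, which runs to 37841873. It held 73 peaks, 97666 covered bp and a maximum of 9.7-fold, with 92664 bp covered in replicate 1 and 82149 bp in replicate 2. Protocadherins are cell adhesion proteins that neurons express in different combinations. Another of the 5 leading domains, from 36896101 to 36981566 on the same chromosome with 44415 covered bp, began before the alpha protocadherin cluster, which starts at 36930184, and reached into it. On chromosome 1, a domain from 88203702 to 88259657 overlapped the Ugt1a genes, which encode enzymes that conjugate glucuronic acid to bilirubin and foreign compounds. It was 83.9% covered, with 45398 bp in replicate 1 and 45657 bp in replicate 2. The remaining 2 lay on chromosome 4, one from 121561634 to 121735745 with the predicted gene Gm12887 and one from 121995143 to 122059951 with no annotated protein-coding gene. The number of domains of at least 5 peaks depended on the gap and the list, with 437 at gaps of up to 1 kb, 2583 from the pooled list, 2163 from the list of replicate 1 and 1620 from that of replicate 2.

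**Figure D2:**
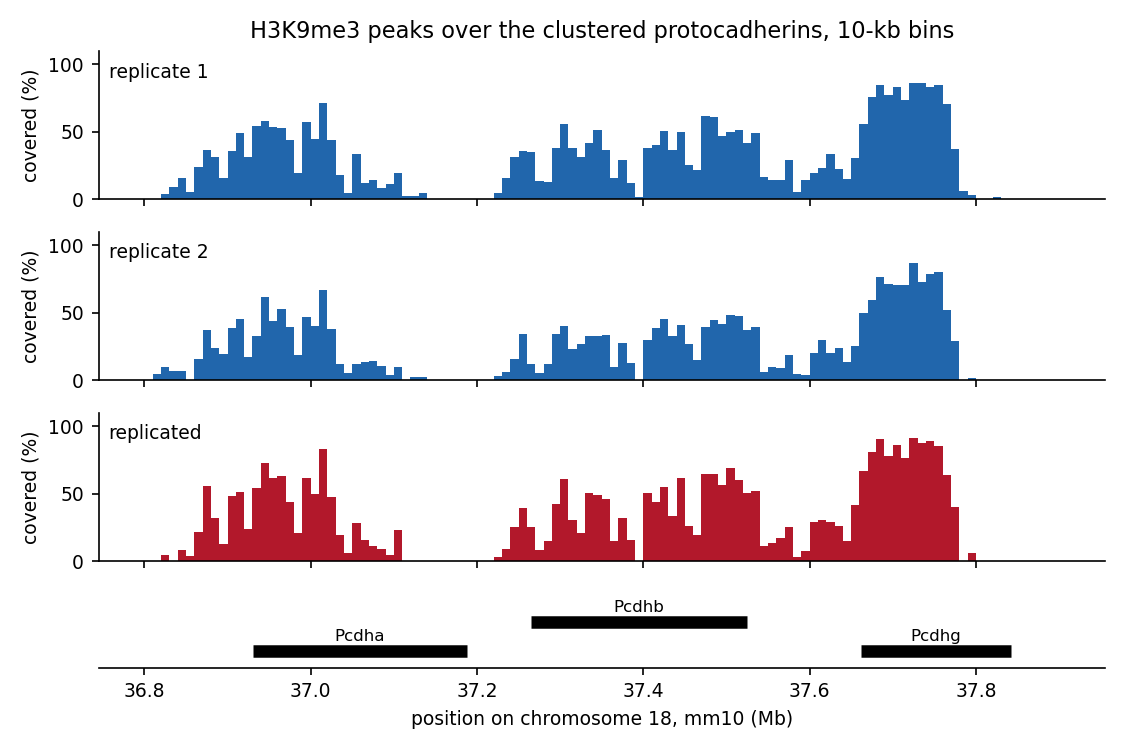
Percent of bases covered by peaks in 10-kb bins (y axes) along chromosome 18 (x axis, Mb, mm10), for replicate 1, replicate 2 and the replicated list, with the extent of the Pcdha, Pcdhb and Pcdhg clusters as black bars. All 3 lists rise over the clusters, and the replicated list covers up to 91.5% of a bin.

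Klf14, a single-exon gene on chromosome 6 (30956023 to 30959078), had its whole body inside 1 replicated peak, with 98.8% ± 1.69 of the body covered in the replicates (SD, n = 2). Its enrichment was 13.32-fold in replicate 1 and 14.14-fold in replicate 2. Among the 10 genes with the highest covered share were 4 secretoglobin genes on chromosome 7, which encode small secreted proteins. Scgb2b24 and Scgb1b24 were covered to 100% each, Scgb1b27 to 94.6% and Scgb2b27 to 92.2%. Coverage was lower in the lists of the replicates, and for Scgb2b24 and Scgb1b24 it differed widely between them. It was 77.8% ± 27.8 for Scgb2b24, 69.1% ± 23.9 for Scgb1b24, 46.9% ± 0.859 for Scgb1b27 and 84.4% ± 1.99 for Scgb2b27 (SD, n = 2). Ugt1a1, the bilirubin-conjugating enzyme, was covered to 94.2%, with 92.5% ± 0.191 in the replicates. The others were Slc25a2, a mitochondrial ornithine carrier (97.2%), the formyl peptide receptor gene Fpr-rs3 (93.1%), Pcdhb15 (91.4%) and the predicted gene Gm21738 (100%). By enrichment of their strongest peak, Klf14 was followed by the zinc finger genes Zfp606 on chromosome 7 at 10.31-fold and Zfp810 on chromosome 9 at 10.09-fold. The next genes, Pcdhga1 to Pcdhga4 and the predicted genes Gm37013, Gm37388 and Gm42416, shared 1 peak of 9.7-fold, because their annotated bodies overlap.

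Of the gene lists fixed before the data were examined, some had more marked genes than shifted peaks gave. Only hindbrain and neural genes passed with fewer, and the remaining lists were not separated from shifted peaks. Zinc finger genes, which encode DNA-binding proteins and many of which repress retrotransposons, held a replicated peak in 161 of 394 cases, or 40.9% (95% Wilson interval 36.1% to 45.8%). Shifted peaks reached 17.2% ± 2.8 (SD over 10000 shifts; ratio 2.38, adjusted permutation p = 0.0013). Within 1 kb of a start site the direction reversed, with 10 of 394 genes (2.54% against 3.32%, ratio 0.764, adjusted permutation p = 1). Zfp936 on chromosome 7 had 44 peaks over 30.5% of its body, and Zfp943 on chromosome 17 had 33 peaks over 17.3%. In the single replicates, 51.3% ± 2.51 of the list had a peak (SD, n = 2), with lower ratios to their own shifts, at 1.41 for replicate 1 and 1.64 for replicate 2. Vomeronasal receptors, the pheromone receptors, were marked in 98 of 329 genes, or 29.8% against 13% ± 3.6 (ratio 2.29, adjusted permutation p = 0.00173), with Vmn2r60 holding 32 peaks and Vmn2r59 holding 16. The larger family of olfactory receptors was marked in 97 of 1135 genes, or 8.55% against 6.22% ± 2.1 (adjusted permutation p = 0.41), with Olfr139 and Olfr403 on chromosome 11 the most covered. Other tests of the olfactory list passed in opposite directions, at 0.551 of the share of other protein-coding genes (exact Fisher test, adjusted p = 3.69e-11) and 1.72 times that of lists matched on gene length (adjusted permutation p = 0.000433). Both take genes as independent, which clustered genes are not. Clustered protocadherins held a peak in 53 of 57 genes (93.0% against 33.6% ± 19; ratio 2.77, adjusted permutation p = 0.00416), although many of these genes overlap and share peaks. The ratios were also lower with the list of replicate 1 alone, at 1.5 for vomeronasal receptors and 1.73 for protocadherins, and with that of replicate 2 alone, at 1.64 and 1.83, and all 4 passed the test. Peaks placed at random individually, which breaks up their clustering, raised the expected share, so that the ratio was 1.33 for zinc finger genes (adjusted permutation p = 0.00649) and 1.17 for vomeronasal receptors (adjusted permutation p = 0.0928), or 1.47 when that placement was also matched for GC content (adjusted permutation p = 0.00519). The vomeronasal call was also lost within 1 kb of a start site (ratio 2.68, adjusted permutation p = 0.0578) and on the longest coding exon (ratio 2.25, adjusted permutation p = 0.253). For protocadherins, individual placement gave a lower ratio of 1.85, and GC-matched placement gave 1.72 (adjusted permutation p = 0.00519).

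Imprinted genes, which are expressed from a single parental copy, held replicated peaks more often than shifted peaks gave. Of 47 genes, 37 held a replicated peak (78.7%, Wilson interval 65.1% to 88.0%), against 25% ± 6.3 after shifts (ratio 3.15, adjusted permutation p = 0.0013). Some of these genes overlap and share peaks, such as Nnat within Blcap and Zrsr1 within Commd1. They are therefore not independent, as the Wilson interval takes them to be. With the list of replicate 1 alone the ratio for imprinted genes was 1.81, and with that of replicate 2 alone it was 2.09. Individually placed peaks gave 1.92, and GC-matched placement gave 1.95 (adjusted permutation p = 0.00519). Gnas, which encodes a signalling G protein subunit, had 4 peaks over 8374 bp with a maximum of 6.01-fold, and Trappc9, whose intron holds the imprinted transcript Peg13, had 8 peaks with a maximum of 5.8-fold. Within 1 kb of a transcription start site, 17 of the 47 genes had a peak (36.2% against 3.5%, ratio 10.3, adjusted permutation p = 0.0013). Germline genes, which encode proteins of meiosis and of the piRNA pathway, were marked in 14 of 30 cases (46.7% against 20.1% ± 7.1; ratio 2.32, adjusted permutation p = 0.0026). With the list of replicate 1 alone the germline ratio was 1.44 (adjusted permutation p = 0.025), and with that of replicate 2 alone it was 1.53 (adjusted permutation p = 0.0442). Near the start site the germline list stood further out, with 11 of 30 genes (36.7% against 2.25%; ratio 16.3, adjusted permutation p = 0.0013). Tdrd1, a Tudor domain gene of the piRNA pathway, had 3 peaks, and Zfp42, a marker of pluripotent cells also in the zinc finger list, had 2, each with a maximum of 4.51-fold. The germline result over gene bodies did not pass the test with individually placed peaks (ratio 1.53, adjusted permutation p = 0.127), with GC-matched placement (ratio 1.62, adjusted permutation p = 0.0779) or when at least 10% of the body had to be covered (ratio 2.97, adjusted permutation p = 1).

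Few genes of the hindbrain and of neurons held a replicated peak, although replicate 1 alone had peaks in 7 of them and replicate 2 alone in 5. Of 44 genes, only Rbfox3, which encodes the neuronal nuclear protein NeuN, held replicated peaks. That share of 2.27% (Wilson interval 0.402% to 11.8%) lay below the 13% ± 4.3 of shifted peaks (ratio 0.175, adjusted permutation p = 0.0221). Rbfox3 had 4 peaks over 0.622% of its body of 421836 bp. With the list of replicate 1 alone the ratio was 0.568 (adjusted permutation p = 0.0448). The pooled list gave 0.245 (adjusted permutation p = 0.000867), and peaks with a −log10 q of at least 2 gave 0.185 (adjusted permutation p = 0.0351). GC-matched placement gave 0.119 (adjusted permutation p = 0.00519). The call was lost with the list of replicate 2 alone (ratio 0.501, adjusted permutation p = 0.0557), with peaks of unique sequence (ratio 0.208, adjusted permutation p = 0.0732) and with peaks that overlapped both replicates (ratio 0.202, adjusted permutation p = 0.0633). It was also lost with windows of 5 kb either side of the gene bodies (ratio 0.635, adjusted permutation p = 0.347) and when only peaks at or above the median enrichment counted (ratio 0.298, adjusted permutation p = 0.35). No gene of the list had a peak within 1 kb of a start site, on the longest coding exon or over at least 10% of the body, but shifted peaks gave only 2.16%, 1.19% and 1.55% there, too few for a lower share to be shown. Genes of other organs also had a low share, at 1 of 30 (3.33%). A low share was thus not shown to be particular to hindbrain and neural genes.

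In the remaining lists the replicated peaks were not separated from shifted peaks, although some passed other tests. No Hox gene, of 39, held a replicated peak (Wilson interval 0% to 8.97%), and shifted peaks gave 5.2% ± 4.8 (adjusted permutation p = 0.525). No histone cluster gene did either, of 67 (0% to 5.42%), against 2.19% ± 3.4 (adjusted permutation p = 0.834). Since 0 is the lowest possible count, the shift tests could not have shown a lower share for either list. Single replicate lists had peaks in 10.3% ± 3.63 of the Hox genes (SD, n = 2). Of 76 ribosomal protein genes, 1 held a peak (adjusted permutation p = 0.41), namely Rpl10l, a testis-expressed copy that is also in the germline list. Markers of other cell types in the tissue were marked in 4 of 24 cases (16.7% against 17.2% ± 7.1, adjusted permutation p = 1), with Pdgfrb of pericytes at 5.62-fold and Tek of endothelium at 3.86-fold. Of 30 genes of other organs, 1 was marked, the liver and kidney regulator Hnf1a (adjusted permutation p = 0.514). Cytochrome P450 family 2, which encodes drug-metabolizing enzymes, was marked in 17 of 48 genes (35.4% against 17.8% ± 8.0, adjusted permutation p = 0.134), with Cyp2b9 and Cyp2c29 the most covered. The list of replicate 1 alone gave ratios that passed for cytochrome P450 family 2 (1.56, adjusted permutation p = 0.025), other cell types (0.429, adjusted permutation p = 0.0247) and ribosomal protein genes (0.231, adjusted permutation p = 0.0247). That of replicate 2 alone passed for ribosomal protein genes (0.157, adjusted permutation p = 0.0442). Against other protein-coding genes, taken as independent, the exact Fisher test passed for Hox genes (adjusted p = 0.00363), histone cluster genes (adjusted p = 5.12e-05), ribosomal protein genes (adjusted p = 0.000135) and cytochrome P450 family 2 (adjusted p = 0.000612). The P450 list also passed against random lists matched on gene length (ratio 3.12, adjusted permutation p = 0.000433), which were drawn gene by gene and do not keep clustering. Over all 21938 protein-coding genes, 15.1% held a replicated peak, against 18.1% ± 0.39 after shifts (ratio 0.838, permutation p = 0.0002, the smallest that 10000 shifts can give). That direction turned when at least 10% of the body had to be covered (ratio 1.31, permutation p = 0.0194) or when the peak had to lie on the longest coding exon (ratio 1.81, permutation p = 0.0002). Individually placed peaks kept the lower direction, with a ratio of 0.542, or 0.531 with GC-matched placement.

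**Figure D3:**
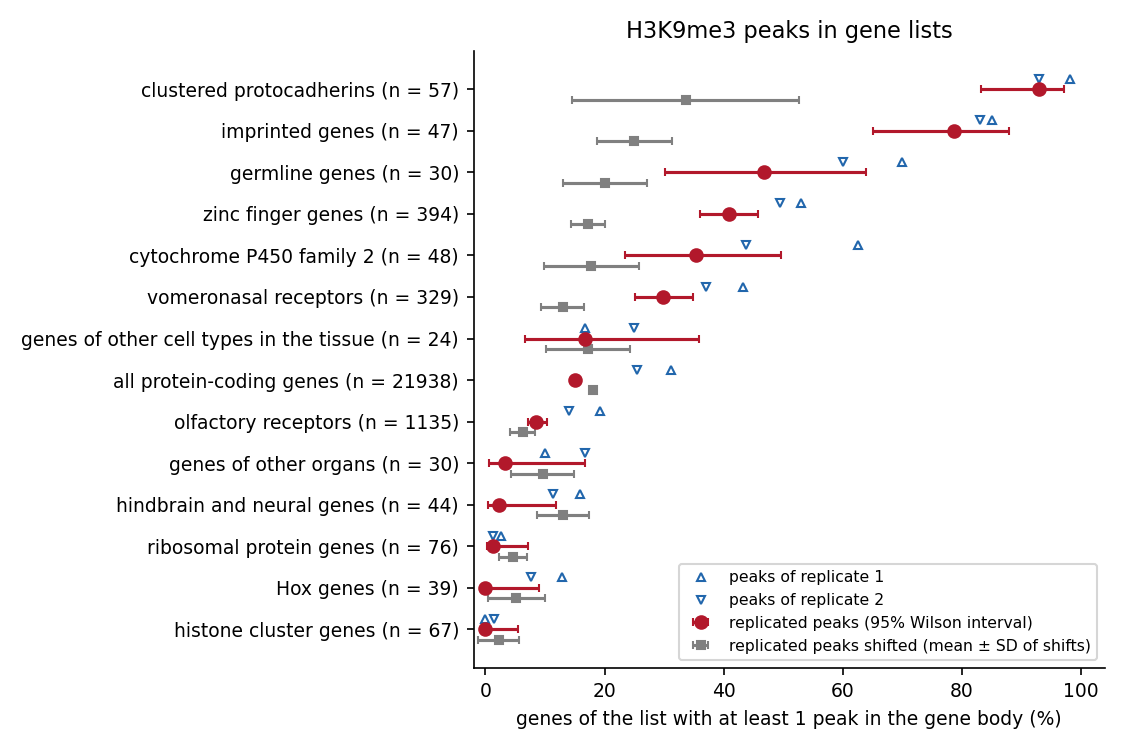
Percent of genes in each list with at least 1 peak in the gene body (x axis, %), for the replicated peaks with 95% Wilson intervals, for shifted replicated peaks as mean and SD of 10000 shifts, and for the lists of replicates 1 and 2 as triangles. Clustered protocadherins stand highest at 93.0%, and Hox and histone cluster genes lie at 0%.

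Zinc finger genes with a peak at only 1 end had it mostly at the transcript end. Among 370 zinc finger genes of at least 5 kb, 81 (21.9%) had a replicated peak over the last kb before the transcript end and 10 (2.7%) had a peak within 1 kb of the start site. In all, 159 of the 370 had a peak somewhere in the body, so many had none over the last kb. A peak stood only at the end in 75 genes and only at the start in 4 (exact two-sided sign test, p = 5.24e-18). The list of replicate 1 gave 82 against 5 genes, and that of replicate 2 gave 87 against 3. Among 17428 other protein-coding genes of this length, 157 had a peak only at the end and 223 only at the start (exact two-sided sign test, p = 0.000832). The start window, 1 kb either side of the start site, was wider than the end window, so this sign test favoured the start. When the end window was made as wide, at 1 kb either side of the transcript end, the other genes turned to 260 against 195 (exact sign test, p = 0.00266). Zinc finger genes stayed at 83 against 3. An excess at the start of other genes is therefore not shown. Genes in a cluster are not independent, so these p-values are too small.

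Endogenous retroviruses begin reverse transcription from a host tRNA, and the binding site of that primer marks their internal sequence. Exact matches to these sites were found in the genome, and replicated peaks within 2 kb of them were counted. Sites for the proline tRNA had a peak in 62 of 174 cases, or 35.6% (Wilson interval 28.9% to 43.0%), against 2.99% after shifts. Sites of the Lys3 type had one in 21 of 62 cases (33.9% against 3.75%), and sites of the Lys1,2 type in 20 of 67 (29.9% against 3.88%). Phenylalanine sites, the type of intracisternal A particles, were the most numerous, with 169 of 1090 marked (15.5% against 3.6%), and the variant glutamine site was marked in 14 of 93 (15.1% against 3.73%). All 5 differences had an adjusted permutation p of 0.002, the smallest that 1000 shifts can give. The leucine site and the other glutamine site had 0 exact matches and were not tested. The excess over shifts was smaller with the other lists. Proline sites, at 11.9 times the shifted share for replicated peaks, stood at 4.92 times with the list of replicate 1 alone, 6.19 times with that of replicate 2 alone and 5.32 times with the pooled list. The ratios for Lys3 were 9.03, 4.14, 5.71 and 5.14 in the same order, and those for Lys1,2 were 7.69, 4.9, 4.7 and 5.03. Phenylalanine sites had ratios of 4.3, 3.25, 3.47 and 3.64, and the glutamine variant had 4.04, 2.58, 3.25 and 2.87.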

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

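The tests with peaks of unique sequence, GC-matched placement and individual placement were chosen after the results they bear on were seen; the test with lists matched on gene length was planned, but its bound was set after its value was seen. Peaks on unlocalized and unplaced contigs stood out, because no comparison used them and they were more than the 3 that a count of 0 allows. The replicated list held 268 peaks on 24 contigs, and a single contig held 71 of them. The density was 50.2 peaks per Mb against 11.1 on the chromosomes, with a median enrichment of 4.2-fold against 3.81-fold. The excess was smaller in the other lists, with 78.9 per Mb against 33.2 in replicate 1, 71.6 against 23.5 in replicate 2 and 71.2 against 35.8 in the pooled list. No explanation of this was tested.

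Zinc finger genes held replicated peaks in 40.9% of cases against 17.2% in shifted peaks. Reads shared between paralogs are argued against as the whole cause, since peaks of unique sequence kept a ratio of 2.41 (adjusted permutation p = 0.0013, with a range of 7.48e-35 to 1 over all alternatives, the exact Fisher test included). Random lists matched on length, drawn gene by gene without the clustering, left a ratio of 3.29 (adjusted permutation p = 0.000433). GC-matched placement gave 1.33 (adjusted permutation p = 0.00519), short of the 1.5 set beforehand to exclude GC content, but individual placement without the match gave the same 1.33, so the match moved the expected share only from 30.7% to 30.8% ± 2.0. The lower ratio under both follows from breaking up the clustering of peaks, and whether these gene clusters share a regional cause stays open. No biological explanation was tested, since the design has 1 group.

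Primer binding sites of endogenous retroviruses were marked more often than shifted peaks gave for all 5 types. With peaks of unique sequence, 5 of the 5 types kept an adjusted p below 0.05, which argues against reads shared between copies as the whole cause. With GC-matched placement 5 of the 5 types had a p below 0.05, at lower ratios than to shifts. These were 7.22 for proline, 6.69 for Lys3, 5.68 for Lys1,2, 2.76 for phenylalanine and 2.65 for the glutamine variant. Individual placement without the match gave 8.56, 6.56, 5.45, 3.14 and 2.97 in the same order, also lower than to shifts. The match itself lowered the ratio only for proline, phenylalanine and the glutamine variant. At most 35.6% of the sites of a type had a replicated peak, and non-unique flanks may be part of the reason. Sites with a peak had a mean of 47.1% unique flanking sequences and sites without had 35%, a difference of 12.1 percentage points (permutation p = 0.0001, the smallest that 10000 permutations can give), and all 5 types had the higher mean in sites with a peak.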

How the results depend on the processing

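Peaks overlapping both replicates, peaks of unique sequence, GC-matched and individual random placement, the longest coding exon and 1 kb either side of the transcript end were alternatives chosen after the data were seen, and the rest were fixed before. Of 385 alternatives to 35 results, 333 kept their side of the threshold, and their direction where it was passed, or moved by less than the replicate spread or the factor of 1.5 for counts. A further 18 passed the threshold anew, 14 no longer passed it, 13 values without a test moved and 7 reversed. Replicate overlap, the 5 primer types, imprinted genes and protocadherins kept their direction and passed the threshold under every alternative run, although values moved, and the ratios of the last 3 to shifts were lower with the list of either replicate alone. Except where stated, the cause was not tested.

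With the pooled list, the ratio to shifts reversed to 0.867 for UTRs and 0.908 for promoters and was 0.113 for ribosomal protein genes, the share on chromosome 7 was 12.3%, and domains of at least 5 peaks numbered 2583 against 881. With 1 replicate left out, the ranges were 12% to 12.7% for chromosome 7, 1620 to 2163 domains of at least 5 peaks, 0.157 to 0.231 for ribosomal protein genes, 0.501 to 0.568 for hindbrain and neural genes, 0.429 to 0.797 for other cell types and 1.39 to 1.56 for cytochrome P450 family 2. Lists above the shifts passed at lower ratios, 1.41 to 1.64 for zinc finger genes, 1.5 to 1.64 for vomeronasal receptors, 1.73 to 1.83 for protocadherins, 1.81 to 2.09 for imprinted genes and 1.44 to 1.53 for germline genes. Without replicate 2 the lists of other cell types and cytochrome P450 family 2 passed the threshold, and without replicate 1 the hindbrain and neural list did not.

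Peaks at or above the median enrichment gave ratios of 1.21 for other exons, 1.3 for UTRs, 1.17 for promoters and 0.298 for hindbrain and neural genes, 32.3% soft-masked bases, 16.8% on chromosome 7 and 433 domains of at least 5 peaks. The ratios of these features and the soft-masked share now passed, as did the soft-masked share of peaks of unique sequence. Peaks of unique sequence gave 27.0% soft-masked bases, 14.8% on chromosome 7, 491 domains of at least 5 peaks and 0.208 for hindbrain and neural genes, and peaks overlapping both replicates gave 0.202 for that list, which did not pass under any of these 3 filters. Gaps of up to 1 kb gave 437 domains of at least 5 peaks, while the number of all domains rose from 16000 to 21080. Uniform placement gave 1.07 for promoters and 33.1% soft-masked bases, the observed values as before, but both now passed, since it loses the clustering and so has a narrower spread. The enrichment correlation was 0.215 with 50% reciprocal overlap and 0.228 with a −log10 q of at least 2.

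For a peak within 1 kb of the start site, the ratio was 0.764 for zinc finger genes, which reversed, 2.68 for vomeronasal receptors, which no longer passed, and 0.0 for hindbrain and neural genes. On the longest coding exon it was 1.81 for all protein-coding genes, which reversed, 2.25 for vomeronasal receptors, which no longer passed, and 0.0 for hindbrain and neural genes. With at least 10% of the body covered it was 1.31 for all protein-coding genes, which reversed, 2.97 for germline genes and 0.0 for hindbrain and neural genes, and with 5 kb either side of the body it was 0.635 for the last. The 3 values of 0.0 say nothing about that list, since shifted peaks marked too few of its genes there for a lower share to pass. Against other protein-coding genes by Fisher's exact test, the ratio reversed to 0.551 for olfactory receptors and was 0.0 for Hox genes, 0.0866 for ribosomal protein genes, 0.0 for histone cluster genes and 2.35 for cytochrome P450 family 2, all 5 of which now passed. These tests take genes as independent, which clustered genes are not. Against random lists matched on gene length it was 1.72 for olfactory receptors and 3.12 for cytochrome P450 family 2, which both now passed. Individual placement gave 1.17 for vomeronasal receptors and 1.53 for germline genes, and GC-matched placement gave 1.62 for germline genes. With 1 kb either side of the transcript end, a window as wide as that at the start, 57.1% of the other protein-coding genes that differed had the peak at the end, which reversed.

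No paired analysis was possible because the samples form 1 group. Depth per library is unknown from peak lists, so a gene without a peak is not shown to lack the mark.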

Other observations

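The tests of gene families, biotypes and 1-Mb bins, and the hypotheses below, were chosen after the data were seen. H3K9me3 was concentrated in few places: the 27 densest of 2737 bins of 1 Mb held 20.3% of the replicated peaks. The densest bin, on chromosome 12 from 114000001 to 115000000, held 357 replicated peaks and no protein-coding gene, and it lies in the immunoglobulin heavy chain variable region. Of the 113 heavy chain V genes on chromosome 12, 33 (29.2%) had a replicated peak, against 0 of 102 V genes on chromosome 6 and 0 of 3 on chromosome 16. Over all 218 V genes, 15.1% were marked against 1.16% ± 1.9 after shifts (permutation p adjusted over 16 biotypes, 0.012). The next bin, on chromosome 13 from 61000001 to 62000000, held 335 peaks over a cluster of placental cathepsins, proteases expressed in the placenta. Of 12 cathepsin genes between 60 and 62 Mb, 11 had a peak, and peaks covered 55.0% of Cts7, 53.5% of Cts6 and 46.5% of Cts8. A bin on chromosome 7 from 33000001 to 34000000 held 282 peaks and 12 secretoglobin genes, and a bin from 17000001 to 18000000 held 251 peaks and 4 genes of the carcinoembryonic antigen family. As whole symbol families, neither passed the shift test. A peak was held by 11 of 34 Scgb genes (adjusted permutation p = 0.231) and 8 of 15 Ceacam genes (adjusted permutation p = 0.325).

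Of 4 classes of pseudogene tested, 3 were marked above the shifts. Processed pseudogenes had a peak in 3.11% of 9940 cases, against 1.36% ± 0.14 (ratio 2.28), and unprocessed pseudogenes in 7.65% of 2642, against 3.17% ± 0.64 (ratio 2.41), both with an adjusted permutation p of 0.00639. Transcribed unprocessed pseudogenes also passed (17.8% against 10.5% ± 2.0, ratio 1.69, adjusted permutation p = 0.00913), and transcribed processed pseudogenes did not (8.45% against 6.72% ± 1.3, ratio 1.26, adjusted permutation p = 0.349). Long intergenic RNAs also passed above the shifts, by a smaller ratio (11.5% against 10.2% ± 0.39, ratio 1.13, adjusted permutation p = 0.00639). The annotation class misc_RNA passed above them too (3.02% against 0.888% ± 0.42, ratio 3.4, adjusted permutation p = 0.00639). The class TEC passed below them (1.62% against 2.6% ± 0.33, ratio 0.622, adjusted permutation p = 0.00913). Of 151 symbol families with at least 15 protein-coding members, 3 lay above the shifts at an adjusted permutation p below 0.05 and 2 below. Those above were the zinc finger genes, the vomeronasal receptors and the beta protocadherins, with a peak in 22 of 22 Pcdhb genes against 3.97% after shifts (adjusted permutation p = 0.0377). The families below were the Ppp symbols, mostly protein phosphatase subunits, with 5 of 75 genes (6.67% against 22.3%, adjusted permutation p = 0.0151), and the Wdr genes of WD repeat proteins, with 5 of 64 (7.81% against 23.0%, adjusted permutation p = 0.0423). Among imprinted genes, Nnat was covered to 76.0%, Cdkn1c to 75.3% and the transcript Peg13 to 70.2%. H19, Igf2 and Dlk1 were among the 10 imprinted genes without a replicated peak, and all 3 had no peak in either replicate.

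A hypothesis for the peaks at the end of zinc finger genes is that they lie on the longest coding exon, which in this family often encodes the zinc finger array. Of 159 zinc finger genes of at least 5 kb with a replicated peak, 110 (69.2%) had a peak on that exon, and rotating the peaks within each gene gave a mean of 53.1 genes. The ratio was 2.07 (permutation p = 0.0002, the smallest that 10000 rotations can give), which goes with the hypothesis, found and tested on the same data. Where that exon lies at the transcript end, any cause that places peaks at the end would also raise the ratio. The test therefore cannot tell the exon from the gene end.

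A further hypothesis was that chromosome 7 owes its density to zinc finger and vomeronasal receptor clusters. Regions within 100 kb of these genes made up 3.23% of the chromosomes and held 16.5% of the replicated peaks. On chromosome 7 they spanned 21.5 Mb, the most of any chromosome, and held 41.8% of its replicated peaks. That was 88.0 peaks per Mb, against 31.9 over the whole of chromosome 7. Without them chromosome 7 still had the highest density, at 21.9 peaks per Mb against 14.3 on chromosome 4. The regions within 100 kb of the listed genes therefore do not by themselves account for its rank. The genes were taken by symbol, so any cluster member under another symbol, or a pseudogene, could remain in the rest. Whether the whole clusters account for the rank was therefore not decided. Without the same regions, the density on chromosome 17 fell from 21.7 to 12.5 per Mb.

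The 10 replicated peaks of highest −log10 q included 3 adjoining peaks over Sfi1 and Drg1 on chromosome 11, from 3184214 to 3200095, and 2 over a ribosomal RNA sequence on chromosome 17, from 39842961 to 39848905. Their median enrichment was 4.41-fold and their median width 2227 bp. Sequence present in several copies could raise such peaks, but the test could not decide this. It counted copies in the reference genome only, so copies that the reference lacks were not seen. The median share of non-unique 32-base sequences was 0.0% in the 10 peaks and also in the other peaks, with means of 12% and 9.26%.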
